A study of Homo sapiens with 18 samples.

How the data were processed

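The samples were 18 ATAC-seq libraries of human monocyte-derived macrophages, an assay in which the transposase Tn5 tags open chromatin. Per the labels, 50,000 cells were used per library, IFN-gamma (2 ng/ml) and TNF (10 ng/ml) were given for 18 h, and libraries had 13 to 16 PCR cycles. The 6 groups are NTC_TNF, NTC_TNF_IFNg, ZC3H13_ctrl, ZC3H13_IFNg, WTAP_ctrl and WTAP_IFNg, with replicates 1 to 3 in each. Per the labels, reads were trimmed, duplicates and mitochondrial reads were removed, Tn5 positions were shifted, and regions were called per library on hg38 at p under 0.01 with at most 300,000 lines kept. The aligner and the peak caller are not given in the sources used here.

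The deposited lists give for each region a −log10 p and a −log10 q, both made by the authors' peak caller. The fold ratio of a region over its background was also made by the authors' peak caller, for each library on its own. The score values, as deposited, are 10 times the −log10 p and were not used here. The summit offset, as deposited, is the distance in bp from the start of a region to its summit, and a region can have several summits. Lists held 173536 to 300000 lines (median 246594.5). No further normalization by the authors is stated in the labels, and each list ranks its own regions.

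Each list was reduced to its 50000 strongest distinct autosomal regions by p, so that all lists had 1 length. The rank score of a region is log2 of the list length plus 1, minus log2 of its rank, and a region outside the list scores 0. Windows were placed on the summits of the listed regions of all libraries, the best-ranked first and without overlap, each reaching 100 bp to either side, and a library has a window where a region covers at least 100 bp of it. Of 108474 windows, 87379 were in at least 3 of 18 libraries and were tested, and 30981 were in all 18. Direction of transcription and exons are not in the annotation used here (GRCh38.p14), so either end of a gene record, with 1 kb on each side, stands for its promoter, and whether a window lies in an exon, intron or UTR is not given. Protein-coding autosomal genes numbered 18973, another 153 records on separate scaffolds were left out, and 12601 gene ends were tested. List members on the X chromosome were left out. Motif shares were not analysed here.

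All 18 libraries were fitted together with limma 3.58.1 in R 4.3.3 (moderated test with a trend, two-sided), with 6 group means and no block. Tables were handled with data.table (1.17.8), Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9. Benjamini-Hochberg adjusted p under 0.05 was the threshold, over all windows or all gene ends of a comparison. The 9 comparisons, the 19 gene lists, the list length and the rule for named genes were set before the data were examined. Lists were tested on gene ends with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, and on windows within 50 kb of a gene with Fisher's exact test against all other windows within 50 kb of a gene (both two-sided, adjusted over lists within a comparison). An exact sign-flip test over 9 pairs used the mean score of each list. Ranking summits in place of regions was added after seeing the data, because regions that join in some libraries give a window the rank of its neighbour. It was done for windows and not for gene ends.

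The genes named in each comparison were WTAP and ZC3H13, the 10 windows with the smallest adjusted p in each direction, the 5 gene ends with the smallest adjusted p in each direction, up to 4 members of each list with the most called windows within 50 kb, and the 5 genes with the most called windows in each direction. IRF1, GBP5, CXCL10, CIITA and SOCS1 were added where a comparison called none, and are also given for gene ends averaged over the arms. Windows with no gene within 50 kb, repeats and a few genes not reported here were left out of the prose, though the counts over named windows and gene ends include them. A window is named after the protein-coding gene with the nearest end, which need not be the gene it acts on.

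The fit was tested on simulated data for IFN-gamma in WTAP macrophages. Scores were drawn independently for each window and library from the measured mean and spread of that window, cut at 0, and changes were added to the draws. Such draws hold no correlation between libraries of the same replicate number or between windows of 1 region. The false calls given here therefore need not hold for the measured lists. At windows with a mean score above 2.5, added changes of 4 were recovered in 47.5% (higher) and 50% (lower) of cases and changes of 2 in 0% and 2.5%. At windows with a mean under 1, a rise of 2 was recovered in 85% and a rise of 1 in 15%. Strong regions therefore had to change far more than weak ones to be called. There were 3 false calls, and at most 1 call with no change added. At gene ends, changes of 4 were recovered in 82.5% (higher) and 72.5% (lower) of cases, with 8 false calls. The window values of 200 windows were recomputed by a second route, with 0 of 3600 values different.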

Results

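Chromatin accessibility was compared in human monocyte-derived macrophages targeted for WTAP or ZC3H13, members of the complex that writes m6A on RNA, and in macrophages labelled NTC, the usual name of a non-targeting control. IFN-gamma was given to each of these 3 arms. Both NTC groups also received TNF, and the labels give no TNF for the knockout groups, so the targeted gene and TNF cannot be separated between NTC and the knockouts. Each of the 6 groups held 3 libraries. The measure was the rank score: a window scores higher the nearer its region stands to the top of the 50000 strongest regions of a library, 1 unit is a factor of 2 in rank, and 0 means that the window is not among them. The score is relative, since all lists have the same length: where some regions rise in rank, others must fall. A lower score can therefore come without a loss of signal. A gene said to gain or lose windows had them called higher or lower. Sequencing depth is unknown, since region lists hold no read counts. The sample titles carry 1 of 3 prefixes, each found once in every group and called replicates 1 to 3 here. The labels do not say what the prefixes mark, such as donors or cultures, and the fit has no block for them, so the p values measure the spread between these libraries. Every library resembled one of its own number most among the libraries of other groups, so the fit leaves out a pairing. Counts with a block are given with the processing, and most of them are larger.

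The region lists of the libraries were unequal in strength, and NTC_TNF_IFNg replicate 3 stood apart. Its list shared 69% to 77.3% of regions with the other lists, which shared 73.6% to 87.5% among themselves. On the first principal component of the window scores (19.8% of the variance) it lay at −323.9, with the others between −90.1 and 56.1, and the median width of its regions was 291 bp against 443 to 745 bp. The −log10 p of the region at rank 50000 was 6.49 in NTC_TNF_IFNg replicate 3 and lay between 14.47 and 34.43 in the other libraries. NTC_TNF averaged 16.65 ± 1.98 (SD, n = 3), ZC3H13_ctrl 32.06 ± 2.11 and WTAP_ctrl 23.77 ± 5.48. Regions within 1 kb of a gene end made up 22.7% to 29.6% of the lists, with the highest share in the same library. In NTC_TNF the −log10 p averaged 16.65 against 27.91 in the 6 knockout libraries without IFN-gamma, and the median region width averaged 491 bp against 662.17 bp. Exact permutation tests (two-sided) gave p = 0.0357 (adjusted 0.286) and p = 0.0119, the smallest that 84 arrangements allow (adjusted 0.143), over 24 tests. With 3 libraries against 3 the smallest p was 0.1.

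IFN-gamma, averaged over the 3 arms, raised the rank of regions near interferon-induced genes. It lowered the rank of others, among them regions near SCD and MARCO. RIPK2, a kinase of NOD signalling, GBP5, a guanylate-binding protein, IFIT3, an antiviral protein, and PPARG, a nuclear receptor of lipid metabolism, each had a window listed in all 3 libraries of every IFN-gamma group and in no library without it. Near RIPK2 (chromosome 8, 89833724) the score rose by 1.39 (SE 0.14, adjusted p = 6.32e-05), to 1.19 ± 0.06 in NTC, 1.64 ± 0.44 in ZC3H13 and 1.33 ± 0.22 in WTAP macrophages (SD, n = 3 each). Positions are window starts in hg38, and adjusted p values are from limma.

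In total 2622 windows were higher and 1864 lower with IFN-gamma among 87379 tested, and 16830 had an unadjusted p under 0.05. The smallest adjusted p among named windows belonged to WAPL, a cohesin release factor, inside whose record (chromosome 10, 86447064) the score rose by 2.36 (SE 0.21, adjusted p = 3.55e-05). A window 10992 bp from the nearest end of CMPK2, an interferon-induced kinase, rose by 1.5 (SE 0.16, adjusted p = 8.52e-05). Windows also rose near LYN, a Src-family kinase (1.78, SE 0.20), DUSP1, a MAP kinase phosphatase (1.65, SE 0.19), ATF3, a stress transcription factor (2.00, SE 0.24), LY6E, an interferon-induced surface protein (1.96, SE 0.24), and GBP5 (1.31, SE 0.14), with adjusted p between 0.000111 and 0.0002. PPARG rose by 2.11 (SE 0.26) and IFIT3 by 1.16 (SE 0.15), both with adjusted p = 0.000269. GCH1, the first enzyme of biopterin synthesis, gained 5 of its 12 windows, SLC15A4, a lysosomal transporter, 6 of 16, KLF6, a zinc-finger factor, 6 of 18, and FOXK1, a forkhead factor, 5 of 19. CD274, an inhibitory ligand of T cells, rose by 0.75 (SE 0.11, adjusted p = 0.000911), JAK2, a kinase of the IFN-gamma receptor, by 1.28 (SE 0.20, adjusted p = 0.00142) and PSMB9, an immunoproteasome subunit, by 1.61 (SE 0.24, adjusted p = 0.000926).

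Among the windows that fell, SCD, the desaturase that makes monounsaturated fatty acids, fell by 1.27 (SE 0.21, adjusted p = 0.00166) and ABCG1, a cholesterol exporter, by 1.00 (SE 0.17, adjusted p = 0.00268). MARCO, a scavenger receptor, fell by 0.47 (SE 0.08, adjusted p = 0.00169), CXCR2, a chemokine receptor, by 0.78 (SE 0.13, adjusted p = 0.00234) and CD74, the class II invariant chain, by 0.74 (SE 0.14, adjusted p = 0.00363). SOX4, a developmental transcription factor, lost 5 of its 10 windows within 50 kb, and MCCC1, a leucine-degrading enzyme, lost 3 of 4. All group means were under 1 in 29.7% of the higher and 37.3% of the lower windows, so many of these regions stand low in the lists. When summits were ranked in place of regions, 94.3% of the higher and 91.6% of the lower windows kept their direction at an unadjusted p under 0.05, while ABCG1 was at −0.41 (adjusted p = 0.0612) and SOX4 at −0.35 (adjusted p = 0.0575). No single library moved the count averaged over the arms past 1.5 times (4803 without NTC_TNF_IFNg replicate 3), whereas leaving out replicate 1, 2 or 3 of all groups gave 251, 1342 and 2570.

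**Figure D1:**
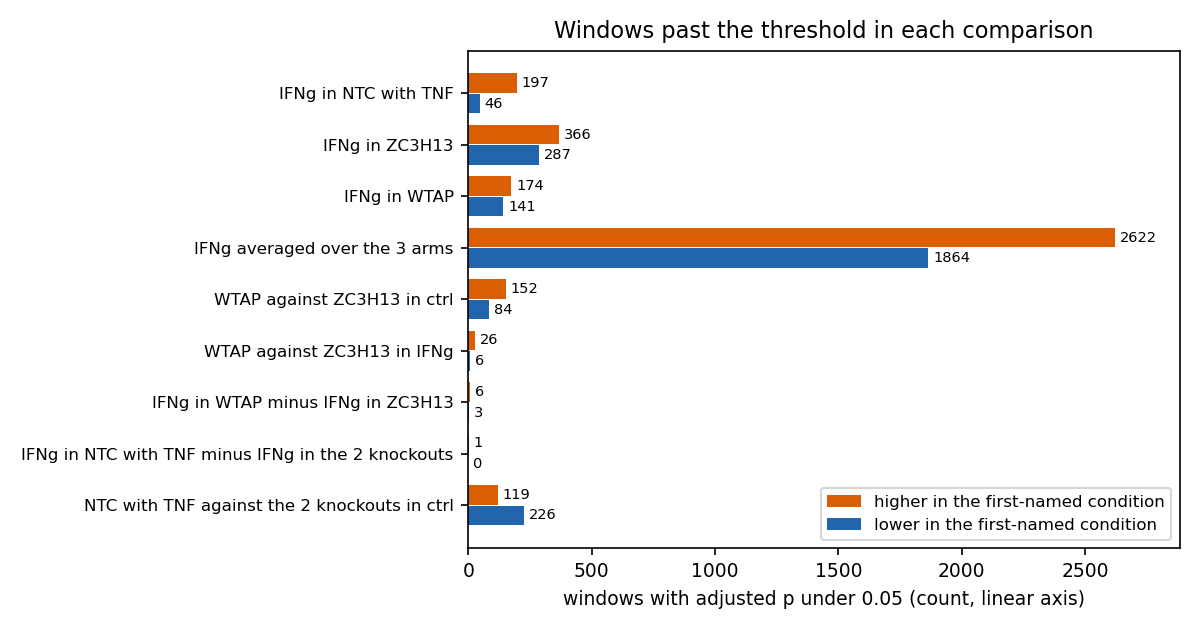
Number of windows (x axis) with a higher or a lower rank score at a limma adjusted p under 0.05 in each comparison (y axis), out of 87379. IFN-gamma averaged over the 3 arms gave 2622 higher and 1864 lower, and the difference between the IFN-gamma effects in WTAP and ZC3H13 macrophages gave 6 and 3.

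At gene ends, the interferon-induced genes GBP4, APOL1, CXCL11 and PLAAT4 rose in rank with IFN-gamma while SCD, CXCR2, OLFML2B and LRTM1 fell. The end of ACKR5, an atypical chemokine receptor, was at 0 without IFN-gamma and reached 1.64 ± 0.25 in NTC, 1.01 ± 0.26 in ZC3H13 and 1.52 ± 0.38 in WTAP macrophages (SD, n = 3 each). Its average rise was 1.39 (SE 0.12, adjusted p = 3.35e-06). VWA3B, a gene of unclear function, rose by 2.19 (SE 0.23, adjusted p = 4.26e-05), GBP4 by 1.90 (SE 0.22), APOL1, a trypanolytic serum protein, by 1.57 (SE 0.18), RCN1, a calcium-binding protein of the endoplasmic reticulum, by 1.44 (SE 0.16) and CXCL11, a CXCR3 ligand, by 1.14 (SE 0.13), the last 4 with adjusted p = 8.08e-05. HNF4G, a nuclear receptor, rose by 1.25 (SE 0.15) and PLAAT4 by 1.16 (SE 0.14), both with adjusted p = 0.00016. LRTM1, a leucine-rich repeat protein, fell by 0.78 (SE 0.10, adjusted p = 0.000263), OLFML2B, an extracellular matrix protein, by 1.01 (SE 0.15, adjusted p = 0.00103) and SCD by 1.27 (SE 0.19, adjusted p = 0.00104). Declines were also called for NEUROD4, USP43, RBMS3, PDZD2 and CXCR2, between −0.52 and −0.78.

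Over all 12601 gene ends tested, 78 were higher and 52 lower with IFN-gamma, and 1357 had an unadjusted p under 0.05. The count of 130 became 86 without ZC3H13_ctrl replicate 3 and 82 without WTAP_IFNg replicate 2. The gene ends of IRF1, CXCL10, GBP5, CIITA and SOCS1, each induced by IFN-gamma in many cells, did not pass: IRF1 moved by 0.10 (SE 0.40, adjusted p = 0.961), CXCL10 by 0.30 (SE 0.10, adjusted p = 0.206) and GBP5 by 0.24 (SE 0.12, adjusted p = 0.484), while CIITA moved by −0.43 (SE 0.23, adjusted p = 0.522) and SOCS1 by 0.39 (SE 0.52, adjusted p = 0.858). Of the 5 windows of GBP5 that rose, the one with the smallest adjusted p lies 37891 bp from that gene and the nearest 1660 bp. Windows near CIITA (chromosome 16, 10843130; 0.39, SE 0.09, adjusted p = 0.0111) and SOCS1 (chromosome 16, 11225437; 0.48, SE 0.13, adjusted p = 0.0375) also rose, 22976 and 28880 bp from the gene ends.

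**Figure D2:**
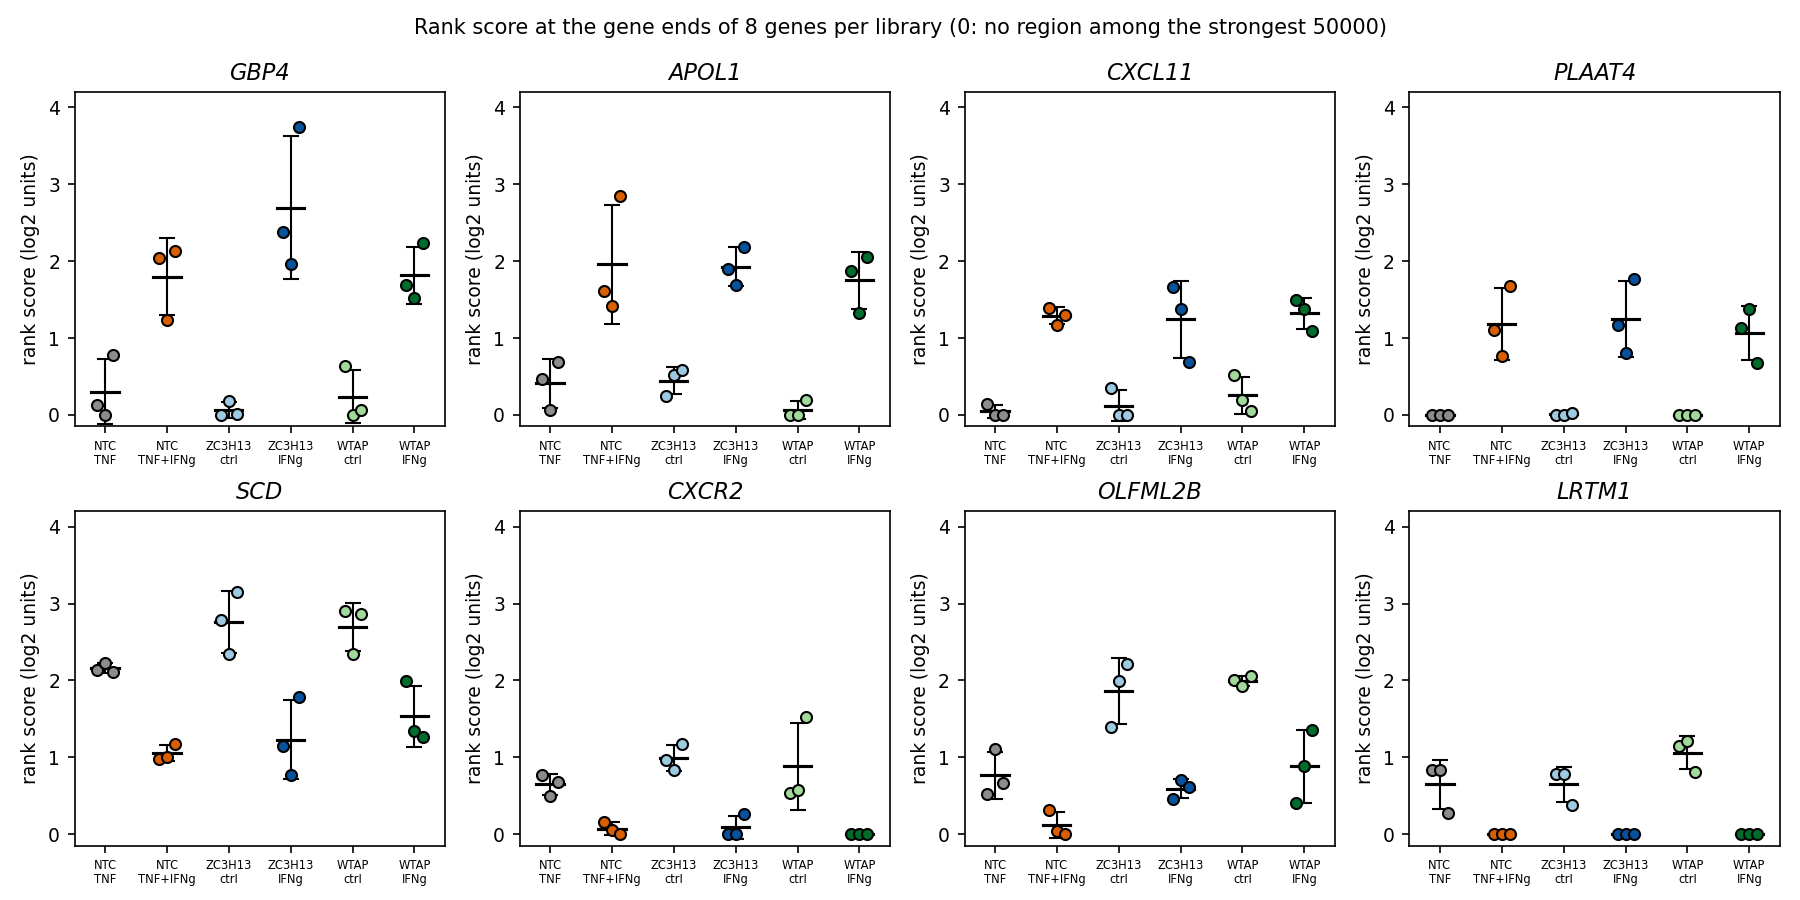
Rank score (y axis, log2 units) at the ends of 8 genes in the 6 groups (x axis), with points for the 3 libraries of a group and the mean ± SD. GBP4, APOL1, CXCL11 and PLAAT4 stand higher with IFN-gamma in each arm, and SCD, CXCR2, OLFML2B and LRTM1 stand lower.

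Interferon genes moved as a group. The 31 tested type I interferon-stimulated genes rose on average by 0.67 and the 41 IFN-gamma response genes by 0.35, in camera tests with adjusted p = 1.53e-13 and 9.17e-10 (0.00714 and 0.00118 with an estimated correlation). EPSTI1 rose by 2.02 (SE 0.28), from 1.01 ± 0.35 to 3.65 ± 1.03 in NTC, from 1.82 ± 0.40 to 4.02 ± 0.49 in ZC3H13 and from 1.61 ± 0.30 to 2.85 ± 0.60 in WTAP macrophages. The neighbouring ends of CMPK2 and RSAD2 rose by 2.38 (SE 0.36), OAS2, an antiviral synthetase, by 2.09 (SE 0.35), and SP110, XAF1, SAMD9L, IFIT1 and IFI44 by 1.18, 1.22, 1.48, 1.51 and 0.99. Of the type I list 9 genes were called over all gene ends, and 11 when adjusted over the list alone. In the IFN-gamma list these counts were 7 and 13 adjusted over the list alone, with ETV7, a repressor of interferon genes, at 2.39 (SE 0.35), PARP14 at 1.14 (SE 0.22), GBP1 at 0.97 (SE 0.16) and SERPING1, the C1 inhibitor, at 0.87 (SE 0.12). The 7 neutrophil genes fell by 0.25 on average (adjusted p = 0.0306 and, adjusted p = 0.0824 with an estimated correlation), with CXCR2 called over all gene ends and 2 members adjusted over the list alone.

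No other list passed the camera test in the average over arms. Nucleic acid sensing and cell death had adjusted p = 0.0691 and 1 of 25 genes higher, DHX58, an RNA sensor of the RIG-I family (1.66, SE 0.28); adjusted over the list alone the count was also 1. Lysosome and lipid metabolism (adjusted p = 0.118) had SCD lower of 22 genes, 2 adjusted over the list alone. Alternative activation (adjusted p = 0.118) had CCL22, a macrophage chemokine, higher (0.81, SE 0.17), antigen presentation class II (adjusted p = 0.467) had HLA-DOA higher (0.64, SE 0.13), and dendritic cell markers (adjusted p = 0.713) had CCR7 higher (0.51, SE 0.11). Adjusted over the list alone these counts were 1 for alternative activation, 1 for class II, and 1 higher and 1 lower for dendritic cell markers. No gene end was called, over all gene ends or adjusted over the list alone, in antigen presentation class I, TNF and NF-kB response, m6A machinery, macrophage identity, cell cycle (adjusted p = 0.657 each), AP-1 and immediate early (0.713), housekeeping (0.657), T cell markers (0.159), B cell markers (0.942) or fibroblast and endothelial markers (0.404). NK cell markers had no gene end that could be tested. The mean and the median difference had opposite signs for TNF and NF-kB response (0.005 and −0.013), cell cycle (−0.001 and 0.042) and B cell markers (−0.011 and 0.011).

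Paired by replicate number, the mean score of the type I interferon list rose in 9 of 9 pairs, by 0.67 (SD 0.23), the IFN-gamma list in 9 of 9, by 0.35 (SD 0.20), and nucleic acid sensing in 9 of 9, by 0.20 (SD 0.17). Lysosome and lipid metabolism fell in 9 of 9 pairs, by 0.24 on average: its mean score was 2.60 in ZC3H13_ctrl and 2.36 in ZC3H13_IFNg, and 2.91 and 2.62 in the WTAP groups. An exact sign-flip test (two-sided) gave p = 0.00391 for each of these, the smallest that the sign flips of 9 pairs allow, adjusted over 18 lists to 0.0176. The neutrophil list fell by 0.25 (adjusted p = 0.0281, exact), and the fibroblast and endothelial list, with 4 gene ends, rose by 0.39 (adjusted p = 0.0468, exact). None of the remaining 12 lists passed, with macrophage identity at −0.04 (adjusted p = 0.396, exact), TNF and NF-kB response at 0.01 (0.988, exact) and T cell markers at −0.20 (0.101, exact). Pairs that share a number are not independent of each other.

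**Figure D3:**
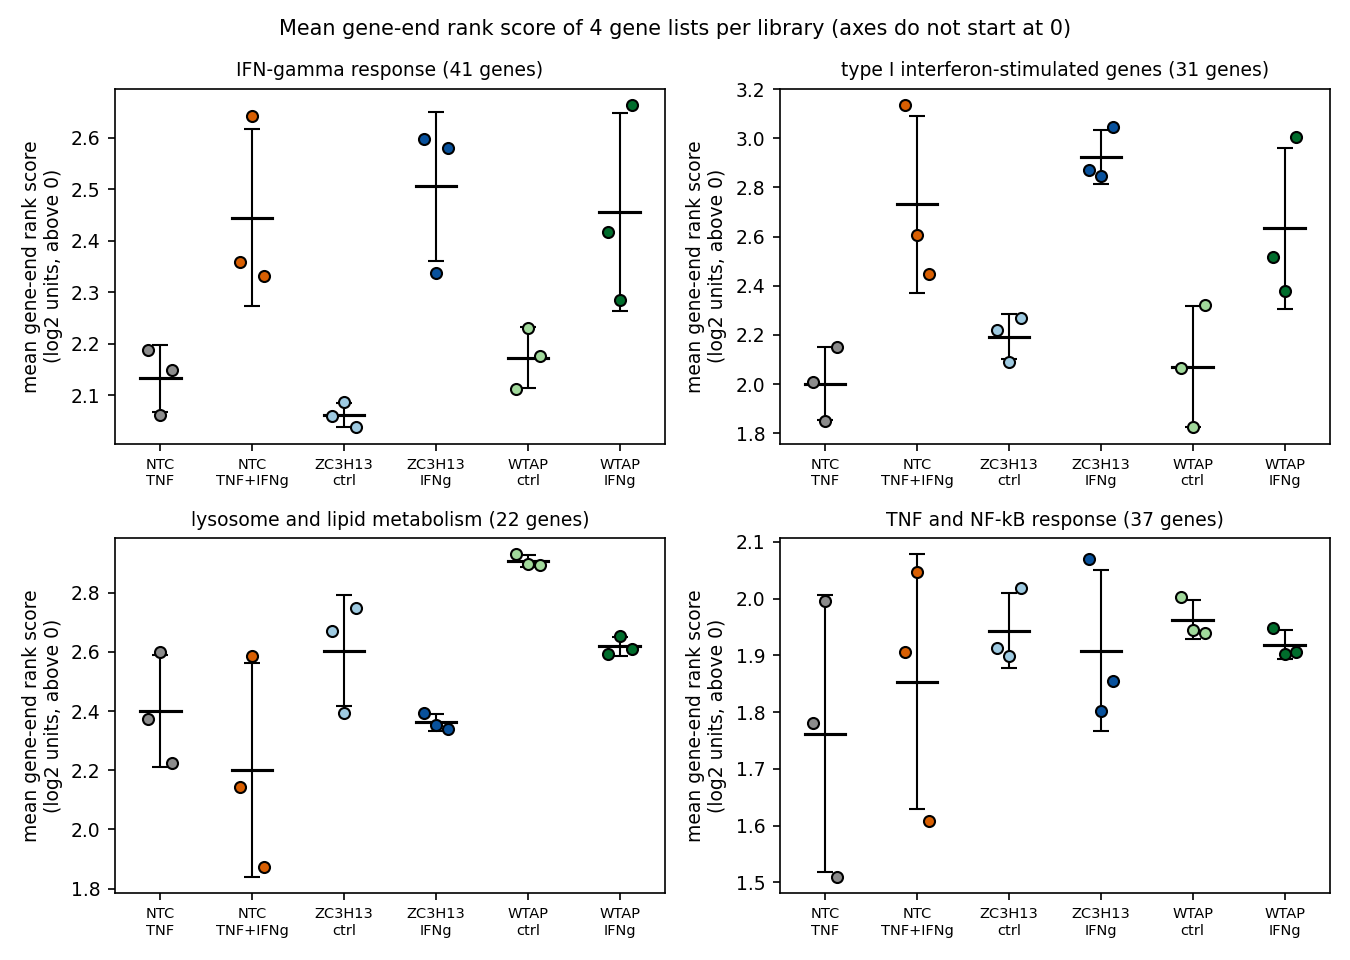
Mean rank score (y axis, log2 units, not starting at 0) of the tested gene ends of 4 lists in the 6 groups (x axis), with points for the 3 libraries of a group and the mean ± SD. The type I interferon list goes from 2.00 to 2.73 in NTC, from 2.19 to 2.92 in ZC3H13 and from 2.07 to 2.63 in WTAP macrophages.

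Windows within 50 kb of the same genes gave a similar order. Near type I interferon-stimulated genes 27 of 124 windows (21.77%) were higher against 2.71% of the others, and near IFN-gamma response genes 38 of 286 (13.29%) against 2.71% (Fisher's exact test, odds ratios 9.97 and 5.51, adjusted p = 2.53e-15 and 2.83e-14). IFN-gamma response genes were also near more lower windows than expected from the rest, 13 of 286 (adjusted p = 0.0259). Windows near nucleic acid sensing and cell death genes were higher in 11 of 148 (adjusted p = 0.0259), among them AIM2, a DNA sensor (0.90, SE 0.16), and GSDMD, a pore-forming protein (1.1, SE 0.21). No other list passed in either direction. Neighbouring windows can lie in 1 region and are then not independent.

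In NTC macrophages with TNF, adding IFN-gamma raised the rank of regions near CMPK2, GBP5 and IFIT3. A window near CMPK2 rose by 1.74 (SE 0.28, adjusted p = 0.0122), one of GBP5 by 1.53 (SE 0.25, adjusted p = 0.0139) and one inside IFIT3 by 1.49 (SE 0.25, adjusted p = 0.0159), the last 2 from 0 to 1.53 ± 0.33 and 1.49 ± 0.61 (SD, n = 3). MTG1, a mitochondrial GTPase, rose by 3.04 (SE 0.37, adjusted p = 0.00747), DNM3, a dynamin, by 3.51 (SE 0.54, adjusted p = 0.0108), BMAL1, a clock transcription factor, by 1.84 (SE 0.28, adjusted p = 0.0106), ELAVL4, an RNA-binding protein, by 2.16 (SE 0.35, adjusted p = 0.0123) and TMEM131 by 2.54 (SE 0.39, adjusted p = 0.0114). GCH1 gained 3 of 12 windows. A window 672 bp from the nearest end of HLA-F, a class I molecule, rose by 3.43 (SE 0.47, adjusted p = 0.00802), and by 1.86 when summits were ranked. EPSTI1, ETV7, LY6E, OASL and CFLAR, an inhibitor of caspase 8, rose by 2.63, 3.38, 2.25, 2.04 and 0.75, while at their summits OASL was at 0.24 (adjusted p = 0.683) and CFLAR at 0.83 (adjusted p = 0.0558). PATL2, SNX13, ZP1, DCTN4, MBP and PIM1, a kinase, fell, with PATL2 at −1.49 (SE 0.20, adjusted p = 0.00802), ZP1, an egg-coat protein, at −1.24 (SE 0.17) and PIM1 at −0.75 (SE 0.12), and MARCO fell by 0.68 (SE 0.13, adjusted p = 0.0392).

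Together 197 windows were higher and 46 lower in the NTC arm, with 8662 at an unadjusted p under 0.05. The calls of each arm rest on the spread shared by all 18 libraries: with only the 6 libraries of an arm fitted, limma called 0 windows in the NTC arm, 3 in the ZC3H13 arm and 0 in the WTAP arm. Without NTC_TNF replicate 1 or 3 the count of 243 became 129 or 134, and without NTC_TNF_IFNg replicate 2 or 3 it became 774 or 451. Of gene ends, ACKR5 passed (1.64, SE 0.21, adjusted p = 0.0018), with 1008 at an unadjusted p under 0.05; without NTC_TNF replicate 2 the count was 4, and without NTC_TNF_IFNg replicate 1, 2 or 3 it was 3, 35 or 10. The IFN-gamma response list rose (adjusted p = 6.56e-05, adjusted p = 0.0248 with an estimated correlation), with 7 genes adjusted over the list alone and 0 over all gene ends. The type I interferon list rose as well (adjusted p = 7.49e-08, but adjusted p = 0.0502 with an estimated correlation), with 8 genes adjusted over the list alone and 0 over all. Windows near type I interferon-stimulated genes were higher in 6 of 124 (Fisher's exact test, odds ratio 25.17, adjusted p = 1.07e-05). Windows in all 3 IFN-gamma libraries and in no library without it numbered 1361, and the opposite 615.

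With IFN-gamma, regions near RALB, a small GTPase, and NUDT3, a hydrolase, rose in rank in ZC3H13 knockout macrophages. So did regions near interferon-induced genes such as GBP4, CD274 and DHX58. The RALB and NUDT3 windows were also listed in all 3 libraries of NTC_TNF_IFNg and in all 3 of WTAP_IFNg. RALB (chromosome 2, 120232374) rose from 0 to 3.52 ± 0.53 (SD, n = 3; SE of the change 0.35, adjusted p = 0.000421). NUDT3 rose by 2.94 (SE 0.39, adjusted p = 0.00642), SAA2-SAA4, an acute-phase read-through gene, by 1.94 (SE 0.26, adjusted p = 0.00642) and ELAVL4 by 2.34 (SE 0.35, adjusted p = 0.00892). MTG1 rose by 2.5 and CRCP, a polymerase subunit, by 1.64. GBP4 rose by 2.63 (SE 0.43, adjusted p = 0.0137), ATF3 by 2.48 (SE 0.41, adjusted p = 0.0139), GBP5 by 1.51, DHX58 by 2.64, CD274 by 1.04, IFIT3 by 1.32 and PPARG by 2.42. CIITA, the activator of class II genes, gained a window 22976 bp away (0.68, SE 0.15, adjusted p = 0.0401), and IDO1, a tryptophan-degrading enzyme, rose by 0.84 (SE 0.16, adjusted p = 0.0263; 0.43 at its summit, adjusted p = 0.549). Lower windows lay near MCCC1 (−1.07, SE 0.18), SYNDIG1 (−0.83, SE 0.12), PDCD1LG2, a second ligand of the PD-1 receptor (−0.75, SE 0.15), MARCO (−0.59, SE 0.13) and ABCG1 (−2.24, SE 0.30, adjusted p = 0.00642). At its summit ABCG1 was at −0.85 (adjusted p = 0.0935). MMD, a membrane protein of maturing macrophages, changed by −3.04 (SE 0.21, adjusted p = 5.13e-06) as a region and by −0.01 at its summit, and SPRYD4 was −3.72 as a region and 0.31 at its summit.

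Among all windows in the ZC3H13 arm 366 were higher and 287 lower, with 9155 at an unadjusted p under 0.05. When summits were ranked, 62% of the higher but 20.9% of the lower windows stayed past the adjusted threshold. The count of 653 became 184 without ZC3H13_ctrl replicate 3, and 185, 309 or 106 without ZC3H13_IFNg replicate 1, 2 or 3. Of gene ends 9 were higher, among them GBP4 (2.63, SE 0.38, adjusted p = 0.00616), VWA3B (2.36), RCN1 (1.53), SERPING1 (1.09), the shared end of DHX58 and KAT2A (2.64) and that of DGKZ and MDK (2.37). The 5 lower gene ends were BCL7A, a chromatin-remodelling subunit (−1.81, SE 0.21, adjusted p = 0.000408), CC2D2A (−1.30), MTUS1 (−1.03), PDZD2 (−0.88) and LRRC25 (−0.82). The gene-end count of 14, with 689 at an unadjusted p under 0.05, became 6 or 5 without ZC3H13_ctrl replicate 2 or 3, and 2, 3 or 4 without ZC3H13_IFNg replicate 1, 2 or 3. Both interferon lists rose, the IFN-gamma response with adjusted p = 2.88e-09 (0.00152 with an estimated correlation) and the type I list with 4.67e-10 (0.0219 with an estimated correlation). GBP4 and SERPING1 were the IFN-gamma genes called, 6 adjusted over the list alone, and in the type I list 0 were called and 8 adjusted over the list alone. Neutrophil markers fell (adjusted p = 0.0121, adjusted p = 0.0475 with an estimated correlation). Near IFN-gamma response genes 11 of 286 windows were higher (Fisher's exact test, odds ratio 10.63, adjusted p = 8.09e-07), and near type I interferon-stimulated genes 5 of 124 (odds ratio 10.93, adjusted p = 0.00253). Windows in 3 of 3 libraries with IFN-gamma and 0 of 3 without numbered 1870, and the opposite 1403.

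With IFN-gamma, WTAP knockout macrophages gained a listed window at CCR7, the chemokine receptor that guides cells to lymph nodes. That window (chromosome 17, 40561300) rose from 0 to 2.28 ± 0.40 (SD, n = 3; SE of the change 0.20, adjusted p = 9.41e-05), and by 0.94 when summits were ranked (adjusted p = 0.0126). It was also listed in all 3 ZC3H13_IFNg libraries, at 0.31 ± 0.25. No NTC library listed it, though a region too weak for the list may lie there. The gene end of CCR7 went from 0 to 0.80 in NTC and from 0.05 to 0.45 in WTAP macrophages. CHIA, a chitinase, rose by 2.54 (SE 0.38, adjusted p = 0.00681), GMEB2, a DNA-binding protein, by 1.46 (SE 0.22, adjusted p = 0.00671), SPAAR by 2.00 (SE 0.39, adjusted p = 0.0347) and FAM50B by 1.82 (SE 0.35, adjusted p = 0.0343). SLC45A4, GALM and LIG1, a DNA ligase, rose by 1.65, 1.38 and 1.20 as regions, and by 0.51 (adjusted p = 0.448), 1.14 (adjusted p = 0.0712) and 1.08 (adjusted p = 0.201) at their summits. CMPK2 rose by 1.56 (SE 0.28, adjusted p = 0.0218), DUSP1 by 1.67, PPARG by 2.33 and ATF3 by 2.12 (SE 0.43, adjusted p = 0.0411). Windows listed in WTAP_ctrl and lost with IFN-gamma lay near DNASE2B, a nuclease (−1.06, SE 0.10, adjusted p = 9.41e-05), PCTP, a phosphatidylcholine carrier (−1.14, SE 0.11, adjusted p = 9.41e-05), and LRRC17 (−0.99, SE 0.10, adjusted p = 0.000195). One near CPSF2, an RNA cleavage factor, fell (−1.27, SE 0.16, adjusted p = 0.00159) but stayed listed in WTAP_IFNg replicates 1 and 3. PRKCD, a kinase C isoform, changed by −3.55 (SE 0.42, adjusted p = 0.000984) as a region and by −0.39 at its summit.

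In all, 174 windows were higher and 141 lower in the WTAP arm, with 8286 at an unadjusted p under 0.05. The count of 315 became 567 without WTAP_ctrl replicate 2 and 878 without WTAP_IFNg replicate 3. Of gene ends, ACKR5 passed (1.52, SE 0.21, adjusted p = 0.00543), with 623 at an unadjusted p under 0.05; the count was 2, 0 or 3 without WTAP_ctrl replicate 1, 2 or 3, and 0, 3 or 10 without WTAP_IFNg replicate 1, 2 or 3. The IFN-gamma response list rose (adjusted p = 4.66e-05, adjusted p = 0.022 with an estimated correlation), with 4 genes adjusted over the list alone and 0 over all gene ends. For the type I list adjusted p = 1.34e-06, but adjusted p = 0.0853 with an estimated correlation, and 0 genes passed over the list alone or over all. No list passed among the windows (Fisher's exact test, 1 of 19 lists at an unadjusted p under 0.05 among lower windows and 0 among higher ones). Windows in 3 of 3 libraries with IFN-gamma and 0 of 3 without numbered 1245, and the opposite 933.

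The arms, which share no libraries, shared more called windows than independent calls would give. NTC and ZC3H13 macrophages shared 81 higher windows where 0.83 would be shared if calls were independent, NTC and WTAP 31 (0.39), and ZC3H13 and WTAP 62 (0.73), with CMPK2, GBP5 and PPARG among windows called in more than 1 arm. Of the windows higher in ZC3H13 macrophages 99.2% also had a positive difference in WTAP macrophages. Fewer lower windows were shared, 4, 1 and 6, where independent calls would share 0.15, 0.07 and 0.46. Calls of the arms are not independent even with no shared effect. All arms use the same spread of a window, from 1 fit, replicate numbers recur in every arm, and neighbouring windows can lie in 1 region. The numbers for independent calls are therefore too low as a measure of chance. Of the windows lower in NTC 52.2% were also negative in WTAP macrophages, and of those lower in WTAP 43.3% were negative in NTC. Across all windows the effects had r = 0.301 between NTC and ZC3H13, 0.261 between NTC and WTAP and 0.425 between ZC3H13 and WTAP; these are correlations across windows, which are not independent replicates.

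At TAP1, a transporter that loads class I molecules, region boundaries moved with IFN-gamma; this locus was picked for a map after its values were seen. The window at 32853158 on chromosome 6, 446 bp from the nearest end of TAP1, changed by −3.34 on average (SE 0.42, adjusted p = 0.00028), by −5.36 in NTC and by −5.5 in WTAP macrophages. In every library of NTC_TNF, WTAP_ctrl and both ZC3H13 groups a region 1198 to 1370 bp wide covered it, at rank 223 to 1845. With IFN-gamma in NTC and WTAP macrophages it was covered in 2 of 3 libraries, by pieces of 307 to 323 bp at rank 24632 to 40901. Neighbouring PSMB9 gained a window at 32854465 (1.61, SE 0.24). At its summit the TAP1 window was at −0.73 on average (adjusted p = 0.0808), so the region score there follows where the region ends.

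**Figure D4:**
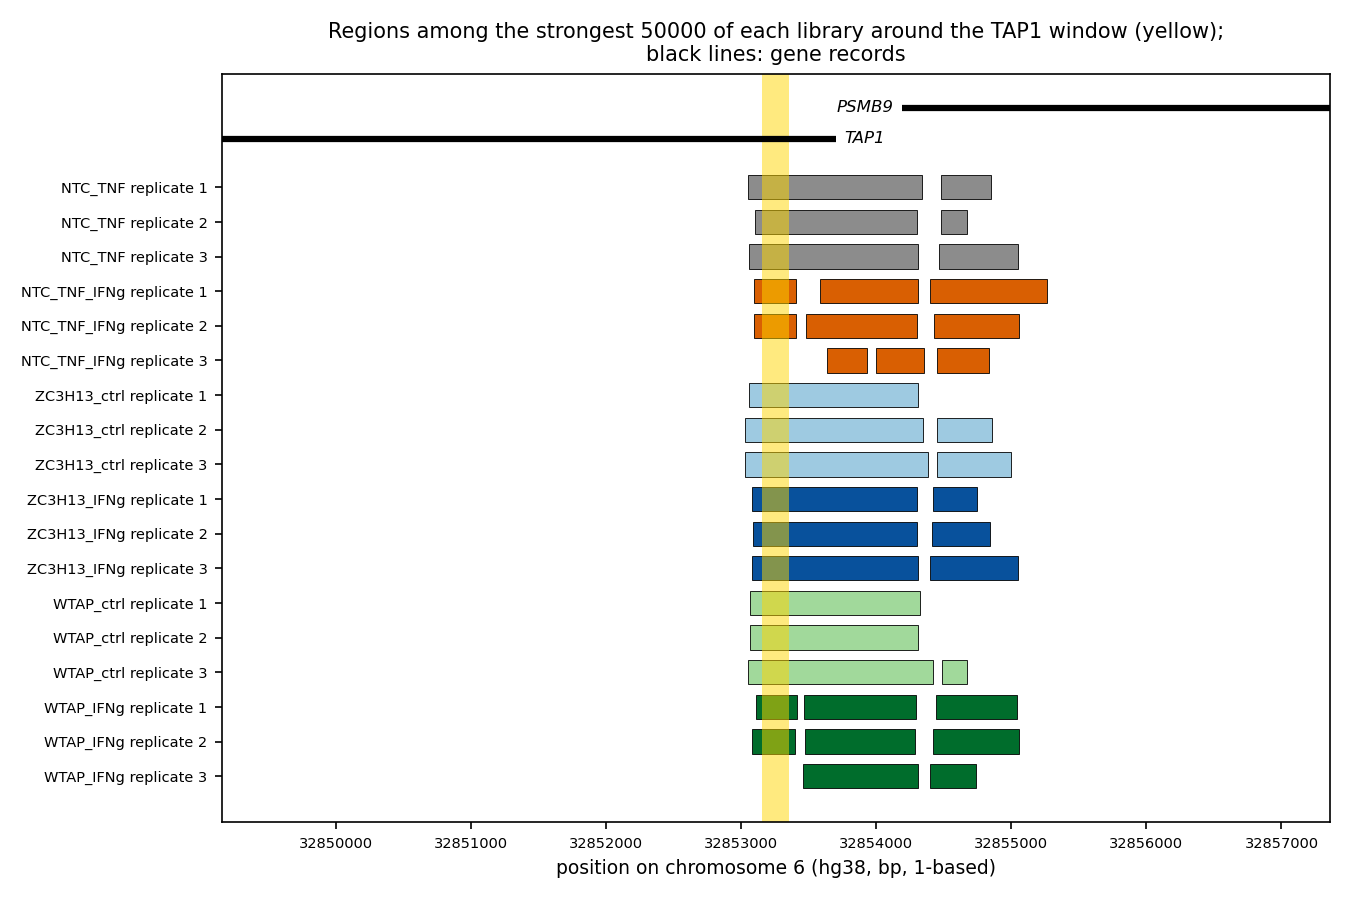
Regions among the 50000 strongest of each of the 18 libraries (rows) between 32849158 and 32857358 on chromosome 6 (x axis, bp), with the gene records of TAP1 and PSMB9 and the TAP1 window marked. A wide region covers the window in the ZC3H13 libraries with IFN-gamma and is split in the NTC and WTAP libraries with IFN-gamma.

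Without IFN-gamma, WTAP and ZC3H13 knockout macrophages differed at single windows, with no gene list past the threshold. WTAP_ctrl held windows near CASP1, the inflammatory caspase, at 1.39 ± 0.46 against 0.11 ± 0.18 in ZC3H13_ctrl (SD, n = 3; difference 1.28, SE 0.24, adjusted p = 0.0289), and near CARD18, a caspase-1 inhibitor, at 0.94 ± 0.18 against 0.05 ± 0.09 (0.90, SE 0.14, adjusted p = 0.00833). GNB5, a G-protein subunit, differed by 2.56 (SE 0.41, adjusted p = 0.0126), THAP6 by 1.85 (SE 0.34, adjusted p = 0.027), TSNAX, an RNA-binding partner of translin, by 1.62 (SE 0.29, adjusted p = 0.0253) and C2orf42 by 1.36 (SE 0.17, adjusted p = 0.00145). LRRC17, a secreted bone regulator, differed by 0.84 (SE 0.10, adjusted p = 0.00145), DCUN1D1, a neddylation factor, by 1.07 (SE 0.15, adjusted p = 0.00371), ARID1B, a chromatin remodeller, by 0.42 (SE 0.08, adjusted p = 0.0291) and SOD2, a superoxide dismutase, by 0.75 (SE 0.15, adjusted p = 0.0371). At summits CASP1 was 1.39 (adjusted p = 0.0511), C2orf42 1.27 (adjusted p = 0.0577), ARID1B 0.51 (adjusted p = 0.0535) and SOD2 0.79 (adjusted p = 0.155).

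Of the 84 windows lower in WTAP 30 lay within 5 kb of a gene end (median distance 11969 bp), and several of those named here were small or 0 when summits were ranked. MMD was −3.12 as a region and −0.09 at its summit, ATIC, a purine enzyme, −4.59 and 0, RPN1, a glycosylation subunit, −5.76 and −0.31, ORAI3, a calcium channel, −2.47 and −0.38, SLC17A9, a nucleotide transporter, −3.01 and −0.74, and TGFBI −1.5 and −0.25. ABCG1 was −1.63 (summit −0.60) and RIPOR2 −0.95 (summit −0.94, adjusted p = 0.0622). RGCC, a cell-cycle regulator, was −1.19 (SE 0.18, adjusted p = 0.00663). At gene ends BCL7A passed, at 0 in WTAP_ctrl and 1.81 ± 0.43 in ZC3H13_ctrl (−1.81, SE 0.21, adjusted p = 0.000408).

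In WTAP against ZC3H13 without IFN-gamma 152 windows were higher and 84 lower in total, with 7094 at an unadjusted p under 0.05, and the count of 236 became 562 or 137 without ZC3H13_ctrl replicate 1 or 3, and 747 without WTAP_ctrl replicate 3. With IFN-gamma 78.3% of the windows higher in WTAP kept a positive difference, 5 of them called, and 52.4% of the lower ones a negative difference, 1 of them called. No list passed (camera, 3 of 18 lists at an unadjusted p under 0.05, smallest adjusted p = 0.151 for lysosome and lipid metabolism; Fisher's exact test, 0 of 19 lists at an unadjusted p under 0.05). In 3 of 3 WTAP_ctrl and 0 of 3 ZC3H13_ctrl libraries 602 windows were listed, and 890 the other way round.

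With IFN-gamma on both sides, WTAP macrophages stood above ZC3H13 macrophages at CCR7 and below them at few windows. CCR7 was at 2.28 ± 0.40 in WTAP_IFNg and 0.31 ± 0.25 in ZC3H13_IFNg (SD, n = 3; difference 1.98, SE 0.20, adjusted p = 0.00032; 0.58 at its summit, adjusted p = 0.385). FRMD4B, a scaffold protein, differed by 1.12 (SE 0.13, adjusted p = 0.00142), FLI1, an ETS factor, by 1.11 (SE 0.16, adjusted p = 0.0188), PEBP4 by 0.54 (SE 0.08, adjusted p = 0.0145), THAP6 by 2.04 (SE 0.34, adjusted p = 0.0385; 1.52 at its summit, adjusted p = 0.323) and VASP, an actin regulator, by 2.92 (SE 0.43, adjusted p = 0.0189; 0.59 at its summit). CROCC at 6.22 (SE 0.93, adjusted p = 0.0216) and GOLGA8B at 0.76 (SE 0.12, adjusted p = 0.0317) belong to gene families with near-identical copies, and have no summit value. ZCCHC2 stood lower in WTAP, by −0.98 (SE 0.14, adjusted p = 0.0115), VRK2, a kinase, by −0.84 (SE 0.13, adjusted p = 0.0331) and RMC1, a lysosomal trafficking factor, by −0.91 (SE 0.16, adjusted p = 0.0491). ATIC, TAP1 and CSTF2T, a cleavage-factor paralogue, were at −4.16, −6.46 and −4.05 as regions, and at −0.63, 0.01 and 0.05 at their summits. The end of NKX6-1, a homeobox gene, was higher in WTAP (1.72, SE 0.27, adjusted p = 0.0441).

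In WTAP against ZC3H13 with IFN-gamma 26 windows were higher and 6 lower in total, with 4619 at an unadjusted p under 0.05. The count of 32 became 18 or 11 without ZC3H13_IFNg replicate 2 or 3, and 104, 62 or 578 without WTAP_IFNg replicate 1, 2 or 3. No list passed (camera, 4 of 18 lists at an unadjusted p under 0.05; Fisher's exact test, 1 of 19 among higher and 2 of 19 among lower windows). In 3 of 3 WTAP_IFNg and 0 of 3 ZC3H13_IFNg libraries 487 windows were listed, and 582 the other way round.

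In a test of the difference itself, the IFN-gamma effect was called as different between the knockouts at few windows, and 24 of 100 groupings of the libraries, the real one included, called as many. It was larger in WTAP than in ZC3H13 macrophages at CCR7 (difference of effects 1.98, SE 0.28, adjusted p = 0.0183, and 0.58 at its summit, adjusted p = 1). The difference was negative near DNASE2B (−1.06, SE 0.13, adjusted p = 0.0106) and PCTP (−1.1, SE 0.15, adjusted p = 0.0153, and −1.2 at its summit, adjusted p = 0.23). There the windows listed in WTAP_ctrl were lost with IFN-gamma. MMD (3.04), SLC17A9 (3.01) and SPRYD4 (5.88) were called as regions, with summit values of 0.01, 0.74 and −0.14. In total the effect difference of the knockouts was higher at 6 windows and lower at 3, with 2361 at an unadjusted p under 0.05. The count of 9 became 102, 23 or 15 without ZC3H13_ctrl replicate 1, 2 or 3, 22, 25 or 32 without WTAP_ctrl replicate 1, 2 or 3, and 17 or 64 without WTAP_IFNg replicate 2 or 3. Between NTC with TNF and the average of the knockouts, NIBAN3, a B-cell gene, passed (3.81, SE 0.48, adjusted p = 0.0312; 0.40 at its summit, adjusted p = 0.882), with 4103 windows at an unadjusted p under 0.05, and 54 of 100 groupings called as many. That count of 1 became 0 without ZC3H13_IFNg replicate 1 or WTAP_IFNg replicate 2. It became 5 or 7 without NTC_TNF replicate 2 or 3, 3, 2 or 7 without NTC_TNF_IFNg replicate 1, 2 or 3, and 17, 3 or 4 without ZC3H13_ctrl replicate 1, 2 or 3. It became 2 without ZC3H13_IFNg replicate 2 or 3, WTAP_ctrl replicate 3 or WTAP_IFNg replicate 3, and 3 without WTAP_IFNg replicate 1. The gene end of BCL7A differed between the knockouts (2.27, SE 0.29, adjusted p = 0.00252). No list differed in either comparison of effects (camera, 0 of 18 lists at an unadjusted p under 0.05; Fisher's exact test, 1 of 19 lists at most). The gene ends of GBP5, CXCL10, IRF1, CIITA and SOCS1 did not differ (adjusted p of 1 in the first comparison and 0.964 to 0.987 in the second).

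Without IFN-gamma, NTC macrophages with TNF stood above the knockouts at windows near REL and CSF1, while BIRC3 and NFKBIA of the same TNF and NF-kB list were lower as regions and the list did not pass (camera, adjusted p = 0.898). REL, an NF-kB subunit, was at 2.00 ± 0.36 in NTC_TNF, 0.61 ± 0.39 in ZC3H13_ctrl and 0.53 ± 0.25 in WTAP_ctrl (SD, n = 3; difference 1.43, SE 0.30, adjusted p = 0.0468). CSF1, the macrophage growth factor, differed by 0.75 (SE 0.16, adjusted p = 0.0494), PIM1 by 0.70 (SE 0.11, adjusted p = 0.0144), PDPK1, a kinase, by 1.28 (SE 0.25, adjusted p = 0.0338), SMCO4 by 2.83 (SE 0.51, adjusted p = 0.0288) and KIAA0513 by 1.73 (SE 0.36, adjusted p = 0.0484). Windows near SULT1A4 (7.18, SE 0.84, adjusted p = 0.00422) and NCF1, an oxidase subunit (3.39, SE 0.56, adjusted p = 0.0208), lie in duplicated sequence, where reads can be placed on the wrong copy. At gene ends ZNF491 (2.12), GPR132, a G-protein-coupled receptor (1.17), EMP3 (0.93), SLC45A4 (3.65), CCDC121 with GPN1 (2.00) and NAA80 with HYAL1 (3.90) were higher, with adjusted p between 0.0226 and 0.0337.

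Lower in NTC_TNF were windows near SCD (−2.51, SE 0.40, adjusted p = 0.0175; summit −1.83), GNB5 (−2.28, SE 0.36, adjusted p = 0.0144) and LRRC17 (−0.58, SE 0.09, adjusted p = 0.0144). At many others the region and the summit parted: PRKCD was −2.34 as a region and −0.41 at its summit, DDAH2, a nitric oxide regulator, −2.72 and −0.61, ATF3 −2.14 and −0.07, HLA-F −2.45 and −0.01, BIRC3, an inhibitor of apoptosis, −2.65 and 0.09, NFKBIA, the inhibitor of NF-kB, −5.42 and −0.62, and EIF4A1, a translation factor, −2.61 and −0.42. At gene ends CNPY3, a chaperone of Toll-like receptors, was at 0.16 ± 0.17 in NTC_TNF against 4.10 ± 0.21 and 3.67 ± 0.24 in ZC3H13_ctrl and WTAP_ctrl (−3.72, SE 0.52, adjusted p = 0.00765). DAG1 (−4.16), STK38L (−3.60), RAB34 (−3.28), COX5A (−2.76), UBXN8 (−2.53), ADAP1 (−2.48) and RAPH1 (−2.17) followed, each with adjusted p = 0.0226. Gene ends were not ranked by summits, so whether region ends moved was not tested for them. Of the lower windows of this comparison within 5 kb of a gene end, 45.3% kept their direction at summits. In total 19 gene ends were higher and 87 lower in NTC_TNF, with 1917 at an unadjusted p under 0.05.

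In total 119 windows were higher and 226 lower in NTC_TNF, with 11607 at an unadjusted p under 0.05. The count of 345 for NTC against knockouts became 191 or 180 without NTC_TNF replicate 1 or 3, and 118 without ZC3H13_ctrl replicate 3. NTC_TNF minus the knockouts was higher at macrophage identity genes than at other gene ends (camera, adjusted p = 0.0151, adjusted p = 0.0474 with an estimated correlation). The mean difference was 0.19 against a median of −0.20 over all gene ends. Their mean score was 1.76 ± 0.05 in NTC_TNF, 1.69 ± 0.06 in ZC3H13_ctrl and 1.44 ± 0.07 in WTAP_ctrl (SD, n = 3 each), so ZC3H13_ctrl lay nearer to NTC_TNF than WTAP_ctrl did. Of these genes 0 of 29 were called over all or adjusted over the list alone. In the TNF and NF-kB list NFKBIE, an NF-kB inhibitor, was lower (−1.17, SE 0.27, adjusted p = 0.0461), and adjusted over the list alone 1 gene was higher and 2 lower. The lysosomal protease CTSL was lower (−1.45, SE 0.33, adjusted p = 0.0461; 1 adjusted over the list alone) and TBP of the housekeeping list higher (2.86, SE 0.63, adjusted p = 0.0391; 2 adjusted over the list alone). No list passed among windows (Fisher's exact test, 0 of 19 lists at an unadjusted p under 0.05 among higher windows and 1 among lower ones). With IFN-gamma on both sides, 76.5% of the higher windows kept a positive and 85.4% of the lower windows a negative difference, while the median went from 1.08 to 0.21 and from −1.62 to −0.55.

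The targeted genes kept accessible ends. The ends of WTAP averaged 5.29, 5.47, 6.78, 5.71, 5.19 and 5.00 in NTC_TNF, NTC_TNF_IFNg, ZC3H13_ctrl, ZC3H13_IFNg, WTAP_ctrl and WTAP_IFNg, and those of ZC3H13 4.10, 4.16, 4.79, 5.03, 5.22 and 4.23. WTAP_ctrl differed from ZC3H13_ctrl by −1.59 at WTAP (SE 0.94, adjusted p = 0.983) and by 0.43 at ZC3H13 (SE 0.91, adjusted p = 1). With IFN-gamma averaged over the arms, WTAP moved by −0.36 (SE 0.54, adjusted p = 0.874) and ZC3H13 by −0.23 (SE 0.52, adjusted p = 0.934), and neither passed in any comparison. Accessibility of a gene end says nothing about whether the edit succeeded.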

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

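Ranking summits, and with it every test of whether region ends had moved, and the test of list strength for IFN-gamma were chosen after the results were seen; the other tests were written before. No test for samples far from their group was run, since groups of 3 are too small for it, though NTC_TNF_IFNg replicate 3 lay apart on the first principal component (−323.9, the others −90.1 to 56.1).

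The IFN-gamma effect differed between WTAP and ZC3H13 macrophages in a test of the difference itself at 9 windows. The effect in WTAP minus that in ZC3H13 macrophages was positive near MMD (3.04, adjusted p = 0.00111), SPRYD4 (5.88, adjusted p = 0.0106) and SLC17A9 (3.01, adjusted p = 0.0106). It was also positive near CCR7 (1.98, adjusted p = 0.0183) and a pair of windows 55 to 56 kb from IL12B (1.04 and 1.02, adjusted p = 0.0106). It was negative near DNASE2B (−1.06, adjusted p = 0.0106), GFRA2 (−1.23, adjusted p = 0.0109) and PCTP (−1.1, adjusted p = 0.0153). The MMD and SLC17A9 windows fell with IFN-gamma in ZC3H13 macrophages, and no WTAP library listed MMD. The DNASE2B and GFRA2 windows were lost with IFN-gamma in WTAP macrophages, and no ZC3H13 library listed them. When summits were ranked, DNASE2B was at −1.2 (adjusted p = 0.0421) and GFRA2 at −1.37 (adjusted p = 0.0421), while MMD was at 0.01, SPRYD4 at −0.14 and CCR7 at 0.58 (adjusted p = 1 each), PCTP at −1.2 (adjusted p = 0.23) and the IL12B pair at 1.11 and 0.91 (adjusted p = 0.337 and 0.444). The gene end of BCL7A differed by 2.27 (adjusted p = 0.00252). Chance cannot be excluded for the 9 windows: 24 of 100 splits of the samples gave as many. The highest other split gave 309, which points to a structure of the samples, and what that split separates was not tested. Here and in every other test by splits, the splits took no account of the replicate numbers.

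Between NTC macrophages with TNF and the knockouts the IFN-gamma effect differed at NIBAN3 (3.81, adjusted p = 0.0312; 0.4 at its summit, adjusted p = 0.882). Chance cannot be excluded there either: 54 of 100 splits gave as many as 1 window and the highest other gave 36, which also points to a structure of the samples.

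The windows that moved with IFN-gamma averaged over the arms were weighed first. For chance, 1 of 100 splits, the real one, gave 4486 windows and the highest other gave 1340, so chance can be excluded; at gene ends it was again 1 of 100, with 130 against 33. Region ends that moved are argued against as the main cause, since 94.3% (95% interval 93.4 to 95.2) of the higher and 91.6% (90.2 to 92.8) of the lower windows kept their direction at an unadjusted p under 0.05 when summits were ranked, and 88.5% and 78.3% at an adjusted one. Such intervals, here and below, count windows as independent, which neighbouring windows are not, so they are too narrow. The summits come from the same libraries in which the windows were called. For list strength, 99.2% of the windows called higher in ZC3H13 macrophages had the same sign in WTAP macrophages, which share no libraries with them. The lists changed in −log10 p by −7.17 with IFN-gamma in ZC3H13 and by 2.54 in WTAP macrophages (exact permutation tests, p = 0.2 and 0.5). This argues against list strength for the higher windows, but only weakly. The gap in WTAP is small against its spread, and a window at 0 without IFN-gamma cannot fall, which raises the share. Within each arm IFN-gamma is the labelled difference between the groups, and this comparison was set before the data were examined. A response to IFN-gamma is therefore the explanation that the design gives for the higher windows, though the single windows were found and tested on the same data. For the lower windows it has less support, since list strength was not tested for them and stays open. Of the windows called lower in ZC3H13, 80.1% were also negative in WTAP macrophages, but of those called lower in NTC 52.2% were.

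The windows that differed between WTAP and ZC3H13 macrophages without IFN-gamma were weighed next. Of all of them 80.9% (75.3 to 85.7) kept their direction at summits, 94.7% (89.9 to 97.7) of the higher ones but 56% (44.7 to 66.8) of the lower ones, and at an adjusted p 55.9% and 6%, so for the lower ones moved region ends and a difference in signal cannot be told apart: the interval includes an even share. The lists differed in −log10 p by −8.28, and the trend of the scores with list strength would give −1.8% (−5.5 to 2) of the difference seen. That trend comes from the other groups, with lower windows counted by the opposite sign. A strength effect shared by higher and lower windows would cancel in part, so the trend cannot decide on strength. The 10 splits are too few for a share under 0.05; the real value was 236 and the highest other 157. The targeted gene may be behind the difference, and that was not tested.

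The windows that differed between NTC macrophages with TNF and the knockouts were weighed last. By the share of 0.05 set before, chance can be excluded, but narrowly and in this test alone: 3 of 84 splits, the real one included, gave as many as 345, the highest other gave 591, and the splits took no account of the replicate numbers. Of all of them 76.8% (72 to 81.2) kept their direction at summits, 95.8% (90.5 to 98.6) of the higher and 66.8% (60.3 to 72.9) of the lower ones, which argues against moved region ends as the cause of most; still, of the lower ones 31.4% stayed at an adjusted p, 10.6% reversed and 45.3% of those within 5 kb of a gene end kept their direction, so for part of them moved ends stay open. The lists differed in −log10 p by −11.27, and the trend with list strength would give 5.4% (−11.2 to 22) of the difference. It was computed with the same signs, so it cannot decide on strength either. TNF and the targeted gene both may be behind the difference, and the design confounds them.

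For comparisons of 3 libraries against 3, the 10 splits are too few for a share under 0.05. The real count and the highest other were 243 and 219 windows for IFN-gamma in NTC, 653 and 32 in ZC3H13 and 315 and 198 in WTAP macrophages, each reached by 1 split, and 32 and 146 for WTAP against ZC3H13 with IFN-gamma, reached by 3. At gene ends they were 1 and 256 in NTC (5 splits), 14 and 3 in ZC3H13 (1 split) and 1 and 1 in WTAP macrophages (3 splits). The 146 windows and 256 gene ends are several times the real counts and point to a structure of the samples. Windows in 3 of 3 against 0 of 3 libraries numbered 1976, 3273 and 2178 in these arms (highest other split 1263, 1083 and 1689), 1492 for WTAP against ZC3H13 without IFN-gamma (1384) and 1069 with it (1566, with 3 of 10 splits as large).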

How the results depend on the processing

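Ranking summits was chosen after seeing the data; the other settings were set before. Counts follow the order in which each paragraph lists the comparisons, leaving out those within 1.5 times the reported count. The cause was not tested except where stated.

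Counts of windows moved with most settings, for IFN-gamma in the NTC arm, ZC3H13 arm, WTAP arm, averaged over the arms, WTAP against ZC3H13 without IFN-gamma, WTAP against ZC3H13 with IFN-gamma, effect difference of the knockouts, NTC effect difference and NTC against knockouts. With 25000 regions they were 30, 83, 93, 936, 73, 8, 0, 0 and 172, and with 100000 regions 916, 2410, 1571, 11470, 903, 169, 50, 4 and 738. With presence among regions at −log10 q above 2 they were 2056, 9047, 3422, 13420, 2353, 1519, 1005, 404 and 3757. Ranked by fold, NTC gave 89, the average 2669, WTAP against ZC3H13 with IFN-gamma 67, the NTC effect difference 0 and NTC against knockouts 114. Asking for 6 libraries gave 183 in WTAP, and 114, 12 and 3 for WTAP against ZC3H13 without and with IFN-gamma and their difference. Ranking summits gave 689 in NTC and 403 in ZC3H13, 102, 21 and 2 for WTAP against ZC3H13 without and with IFN-gamma and their difference, and 0 for the NTC effect difference. Presence in place of rank gave 1099, 2591, 1169, 631, 463, 216, 364 and 851, the average excepted. Fitting only the libraries compared, with fewer samples for the spread by construction, gave 0, 3, 0, 22, 0, 4 and 80, the average and the NTC effect difference excepted. The limma counts of 0 stand beside 8662, 8286, 4619, 2361 and 4103 at an unadjusted p under 0.05 with the reported settings.

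At gene ends (NTC arm, ZC3H13 arm, WTAP arm, averaged over the arms), 25000 regions gave 6 in ZC3H13 and 60 on average, 100000 regions 4, 28 and 10 in the arms, and −log10 q above 2 20, 35, 16 and 51. Ranked by fold NTC gave 3 and WTAP 2, ends within 5 kb 7, 26, 9 and 205, presence 19, 35, 19 and 64, and only the libraries compared 0, 8 and 0 (1008 and 623 at an unadjusted p under 0.05 in NTC and WTAP with the reported settings). Windows in 3 of 3 against 0 of 3 libraries (the arms, then WTAP against ZC3H13 without IFN-gamma and WTAP against ZC3H13 with IFN-gamma) numbered 816, 1331, 931, 665 and 502 with 25000 regions, 3897, 6829, 4536, 3313 and 2398 with 100000, and 3902, 11785, 6735, 6127 and 3595 with −log10 q above 2. An estimated correlation left 1 list in NTC and 1 in WTAP. An overlap of 1 or 150 bp left each of 14 counts within 1.5 times, as did distances of 10 and 100 kb for the 4 list results.

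The replicate numbers stand for 3 title prefixes that recur in every group, and the labels do not say what they mark. Of 45 pairs with the same number 30 correlated above 0.1 (median 0.143, against −0.072 for other numbers); the reported fit had been set without a block before the data were seen. A block on the number gave 486, 1057, 519 and 758 windows (NTC arm, ZC3H13 arm, WTAP arm, and NTC against knockouts) and 19, 36, 11 and 210 gene ends (the same arms, then averaged over the arms), with 248 in place of 106 gene ends for NTC against knockouts. Among the libraries of other groups, 18 of 18 libraries correlated best with one of their own number. The numbers therefore pair libraries, and the reported p values leave that pairing out. Of the 196 windows and gene ends with the smallest adjusted p of their comparison and direction, 194 stayed past the threshold with the block.

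Leaving out libraries gave windows from 0 to 774 in the NTC arm, 33 to 646 in the ZC3H13 arm, 50 to 878 in the WTAP arm and 251 to 4803 averaged over the arms. For WTAP against ZC3H13 without IFN-gamma they ranged from 1.0e+02 (rounded to 2 digits) to 747, for WTAP against ZC3H13 with IFN-gamma from 6 to 578, for the effect difference of the knockouts from 8 to 102, for the NTC effect difference from 0 to 17 and for NTC against knockouts from 18 to 502. Gene ends ranged from 0 to 35, 0 to 11, 0 to 10 and 2 to 153, and 3 of 3 against 0 of 3 from 4574 to 5480, 6327 to 6878, 4778 to 5724, 3285 to 5006 and 2754 to 4472, larger by construction with fewer libraries. Of these 196 items 62, 77 and 116 stayed past the threshold without replicate 1, 2 or 3 of all groups.

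With summits ranked, 87 of the windows among these stayed past the threshold, 42 kept their direction only and 9 reversed or came to 0. These were SPRYD4 in ZC3H13 (0.31), ATIC (0) without IFN-gamma, TAP1 (0.01) and CSTF2T (0.05) with it, SPRYD4 for the effect difference (−0.14), and EIF4A1 (0.17), MMD (0.25), DNAAF9 (0.06) and ZNF212 (0) for NTC against knockouts. Windows named for other reasons, such as BIRC3 (0.09), are not in these counts. At TAP1 the regions themselves show a split; for the others the cause was not tested. Depth is unknown from region lists, so its effect on weak regions cannot be given.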

Other observations

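No test in this part was chosen after the results were seen, since it reports values only.

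Inside the gene record of SOD2, which also holds the record of the targeted gene WTAP, windows at 159716295 and 159716787 on chromosome 6, about 10 kb from WTAP, rose with IFN-gamma averaged over the arms, by 1.42 (SE 0.33, adjusted p = 0.0181) and 1.63 (SE 0.34, adjusted p = 0.00902). The second went from 2.99 ± 0.68 to 4.66 ± 0.66 in NTC, from 1.98 ± 0.47 to 4.08 ± 1.29 in ZC3H13 and from 3.09 ± 0.39 to 4.2 ± 0.23 in WTAP macrophages (SD, n = 3 each). The windows at the ends of the WTAP record did not pass, at −0.36 (SE 0.55, adjusted p = 0.768) and −0.74 (SE 0.74, adjusted p = 0.626), nor did any listed window of ZC3H13.

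Several genes had windows that moved in opposite directions with IFN-gamma. ETV7 gained a window at its end (2.71, SE 0.37) and lost one inside the record (−0.86, SE 0.18, adjusted p = 0.01), IRF8, a myeloid transcription factor, gained one 38608 bp away (0.79, SE 0.22) and lost one inside (−0.95, SE 0.19), and PIM1 gained one 14905 bp away (2.04, SE 0.30) and lost one 12013 bp away (−0.35, SE 0.07). KLF9 gained a window (1.01, SE 0.18) while another was at −1.13 as a region and −0.04 at its summit.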
